A study of Mus musculus with 6 samples.

How the data were processed

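Gene expression was measured in mouse breast cancer cells that had been sorted by the surface proteins CD24 and CD29. CD24 is a mucin-like glycoprotein encoded by Cd24a, and CD29 is the integrin beta-1 chain encoded by Itgb1. Per the labels, the sorted cells formed 2 groups, positive for both proteins (CD24+CD29+) or negative for both (CD24-CD29-), with 3 arrays each. The series' design text calls the sample sets independent and biological, and nothing else used here says whether they came from separate cultures, sorts or animals. The p-values therefore measure the spread between these samples, part of which may be technical. Per the labels' protocols, the cells were cultured in serum-containing medium, total RNA was extracted with Trizol, and biotin-labelled cRNA was made by the manufacturer's protocol and hybridised to Affymetrix Mouse430_2 arrays, on which each gene is read by 1 or more probe sets placed mostly toward the 3' end of its transcript.

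The deposited values were on the log2 scale. Per the submitters' processing notes they were made with RMA, which subtracts background, normalizes between arrays and summarises the probes of each probe set, and with Partek software. The versions, the settings and the order of these tools are not given in the sources used here. All 6 arrays had the same mean over 45101 probe sets, 6.93, but not the same spread. The standard deviation over probe sets was 2.12 ± 0.02 in CD24+CD29+ arrays and 2.02 ± 0.01 in CD24-CD29- arrays (SD between arrays, n = 3 each; exact permutation test, 2-sided, p = 0.1, the smallest p that 3 arrays against 3 can give). The values came with no detection calls, so no gene was called absent and no fold was treated as a bound. Background in RMA values compresses the differences of dim genes, so their folds are understated. The highest value on an array was 14.9 to 15.0, and differences of probe sets near that limit can be compressed too: for the added dap control RNA the probe sets at the 3' end, with means of 14.2 and 14.3, differed between the groups by 0.46 and 0.42, against 1.37 and 1.41 for those at the 5' end. The lower quartile of an array lay between 5.20 and 5.41.

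Probe sets were named through the platform's annotation table, which can be old. Of the probe sets, 64 were controls. Of the others, 34945 had exactly 1 gene symbol, 932 had several and 9160 had none in the table. The Entrez identifiers of 34741 single-symbol probe sets were found in a RefSeq gene table of the mouse assembly GRCm38.p6, and no symbol had to be updated. The sources used here name no genome build for the array, so no coordinates are given and genes are identified by symbol and probe set. A gene was represented by its single-symbol probe set with the highest mean over the 6 arrays, leaving out probe sets ending in _x_at, which can cross-hybridise, where the gene had another. This gave 18193 genes, of which 9010 had more than 1 probe set.

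The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no block, no trend) on the values as deposited. Differences are CD24+CD29+ minus CD24-CD29- on the log2 scale, with the standard error (SE) of the fit. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05, and a size criterion of 2-fold was used beside it. The number of arrays limits the precision. The median SE was 0.06, and the smallest difference that passed was 0.10. In a test on simulated data with the spread of this comparison, over 18193 genes of which 50 were changed at each size, the fit recovered 16% of the genes changed by 0.25, 66% of those changed by 0.5, and 100% of those changed by 1 or by 2. Of 146 calls, 5 were false. In the real comparison 70.8% of genes passed, far more than were changed in the simulation, so the adjusted threshold was stricter in the simulation. The recovered and false shares are therefore not those of the real comparison.

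Before the data were examined, 37 gene lists were written. They cover PI3K and mTOR signalling and the actin cytoskeleton, which the series' title names; mammary lineages, adhesion, matrix, signalling, proliferation, stress and metabolism; and markers of other cell types that a culture or a sort could hold (fibroblasts, leukocytes, endothelial cells, adipocytes and erythroid cells). The list of the pair of sort genes was too short to test, since 5 measured members were required, which left 36 lists. Of 1262 distinct genes in the lists, 1166 were measured, and the others were not analysed here. Each list was tested against all other genes with limma's camera, 2-sided, with a preset correlation of 0.01 between genes, and adjusted over the 36 lists. An estimated correlation and limma's fry were run beside it. The median of each list was also set against the medians of 10000 random lists of the same size, each member replaced by a gene from the 101 nearest in mean level. Members were drawn separately, so correlation between a list's genes is not carried over and the range of these medians can be too narrow. The percentiles were not adjusted over the 36 lists. Some lists share genes. For example, 6 fibroblast markers also stand in the list of collagens, laminins and matrix.

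The rule for the genes named in the text was also fixed before the data were examined. It took the 12 genes with the largest positive and the 12 with the largest negative differences among those past the threshold whose groups did not overlap, passing over clones and predicted genes; Cd24a and Itgb1; and the 4 members with the smallest p from each list past the threshold and from the lists for PI3K, actin, integrins, basal, luminal, mesenchymal and stem cell genes in any case. This named 94 genes, of which 63 had more than 1 probe set. Genes outside this rule are marked as chosen after their values were seen.

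The alternatives fixed before the data were examined were a block for the replicate number, a pair of filters on dim genes, quantile normalization, median centring, a variance trend with and without robust estimation, the mean of a gene's probe sets, keeping probe sets ending in _x_at, testing every probe set, an equal-variance test per gene, and leaving out each array in turn. Ranges of a list's adjusted p over other settings are those with the preset correlation. Cyclic loess between arrays and scaling to the poly-A control RNAs were added after seeing the data. The figures were drawn with matplotlib 3.10.9. Samples with the same replicate number were not treated as pairs.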

Results

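The data were 6 arrays of sorted mouse breast cancer cells, 3 of CD24+CD29+ cells and 3 of CD24-CD29- cells. The series' labels describe the cells as breast cancer stem cells, and its title ties their spread and survival to the cytoskeleton and to PI3K and mTOR signalling. Arrays of a group correlated at r = 0.997 to 0.998 over genes, and arrays of different groups at r = 0.974 to 0.979, where genes are not independent replicates. The first principal component, which held 92.0% of the variance, separated the groups.

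The first question was whether the RNA of the sort proteins differed between the sorted groups. Itgb1, the gene of CD29, was higher in CD24+CD29+ cells, at 10.94 ± 0.05 against 10.06 ± 0.03 on the log2 scale (mean ± SD, n = 3), a 1.83-fold difference (log2 0.87, SE 0.04, limma adjusted p = 2.5e-06). Cd24a was abundant in both groups, at 12.79 ± 0.03 in CD24-CD29- cells (SD, n = 3), and its difference was small, 1.16-fold higher in CD24+CD29+ cells (log2 0.21, SE 0.04, limma adjusted p = 0.0026). The probe sets of Cd24a differed in direction. A second was higher in CD24+CD29+ cells by 0.20, whereas the one ending in _x_at was lower, at -0.45, and the mean of the 3 probe sets gave a difference of -0.01 that did not pass. Of the 6 probe sets of Itgb1, 1 dim probe set went the other way, by -0.17.

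The main comparison asked which genes differed between the groups. CD24+CD29+ cells had higher RNA of Bpifa2 and Chia1, a secreted lipid-binding protein and an acidic chitinase, by 35.3-fold and 30.9-fold. They also had higher RNA of the matrix-degrading enzymes Mmp10 and Mmp12, of the collagen crosslinking enzyme Lox and of the collagen VI chain Col6a1. CD24-CD29- cells had higher RNA of Tent5c, a poly(A) polymerase, by 26.3-fold, of Ceacam10 by 13.5-fold, and of the lysosomal protease Ctss by 6.43-fold. In all, 12889 of 18193 genes (70.8%) passed the threshold, 6251 higher and 6638 lower in CD24+CD29+ cells, and 8538 of these differed by less than 0.5 on the log2 scale. At least 2-fold differences were found for 849 genes, 547 higher and 302 lower, and at least 4-fold differences for 25 and 39. Of the 849 genes, 80 had another probe set past the threshold in the opposite direction.

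Among the 12 largest rises, Bpifa2 stood at 11.25 ± 0.02 against 6.11 ± 0.05 (log2 difference 5.14, SE 0.04, limma adjusted p = 2.5e-09; 3 arrays per group), and Chia1 at 10.51 ± 0.05 against 5.57 ± 0.07 (4.95, SE 0.05). Mmp10 was 8.80-fold higher, Dcpp1, a secretory protein with near-identical copies that its probe set may also read, 7.21-fold, and the secreted C1q-related protein gene C1qtnf3 6.88-fold. Lox was higher by 5.57-fold, the keratin gene Krt6b by 5.46-fold, Dynap by 5.34-fold, Col6a1 by 5.15-fold, Mmp12 by 4.96-fold and the sheddase gene Adam8 by 4.66-fold. Thop1, which encodes a peptidase, was 5.34-fold higher on its main probe set, and its other probe set went the other way. Among the 12 largest falls, Tent5c stood at 5.55 ± 0.21 against 10.27 ± 0.04 (-4.72, SE 0.10) and Ceacam10 at 5.58 ± 0.09 against 9.34 ± 0.03 (-3.76, SE 0.05). Klhl13, an adaptor of a ubiquitin ligase, was 9.07-fold lower, the adhesion receptor gene Adgrf5 8.95-fold, Reep1 and Rtn1, which encode membrane-shaping proteins of the endoplasmic reticulum, 8.78-fold and 8.32-fold, and Rragd, a GTPase that controls mTORC1 at the lysosome, 8.13-fold. Mmp16 was lower by 7.86-fold, Ecrg4 by 7.48-fold, the monooxygenase gene Fmo2 by 6.48-fold and Ctss by 6.43-fold. Adi1 was 6.28-fold lower on its main probe set, but it was higher by 0.40 on its brightest probe set, which ends in _x_at.

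**Figure D1:**
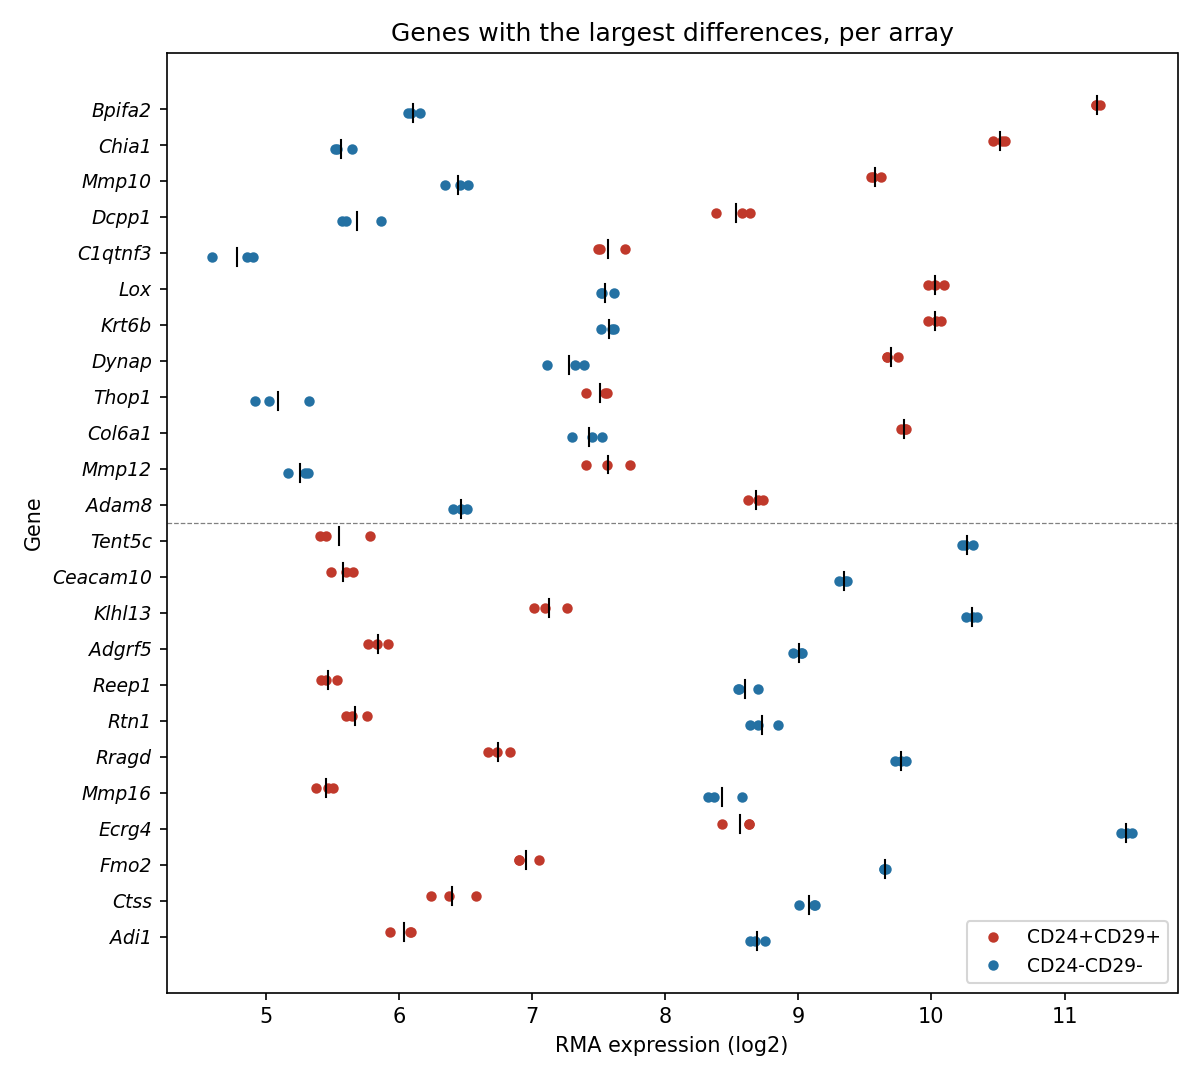
Log2 RMA expression (x axis) of the 12 genes with the largest rises (above the dashed line) and the 12 with the largest falls (below it) in CD24+CD29+ cells; each point is 1 array, red for CD24+CD29+ and blue for CD24-CD29-, and each black tick is a group mean of 3 arrays. The arrays of a group lie close together against the gap between groups, as for Bpifa2 at 11.25 against 6.11 and Tent5c at 5.55 against 10.27.

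The groups did not overlap for 13397 genes (73.6%, where chance gives 10%). The higher and lower genes were not spread evenly over expression levels. The median difference was -0.22 for genes with a mean of 5 to 6 and -0.13 for 6 to 7, against 0.25 for 8 to 9 and 0.21 for 9 to 10. Of the 849 genes with at least a 2-fold difference, 64.4% were higher in CD24+CD29+ cells, and this share was 50.5% of 750 genes after quantile normalization and 50% of 746 genes after cyclic loess, but 71.8% of 916 genes after median centring, which gave 6931 higher and 5535 lower genes in all (55.6% higher, against 48.5% as deposited). The added poly-A control RNAs were higher on CD24-CD29- arrays by a median of 1.24. Scaling to them moved the median of all genes from -0.04 to 1.22, the share of higher genes among all those past the threshold from 48.5% to 99.3%, and that among at least 2-fold differences to 99.8%. Directions in the text are therefore those on the deposited scale, relative to the other genes, and lower genes whose difference was smaller in size than that shift turn positive under this scaling. The scaling adds the same amount to the difference of every gene, so it left each list's median relative to all genes as it was, also where it ended a camera call.

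**Figure D2:**
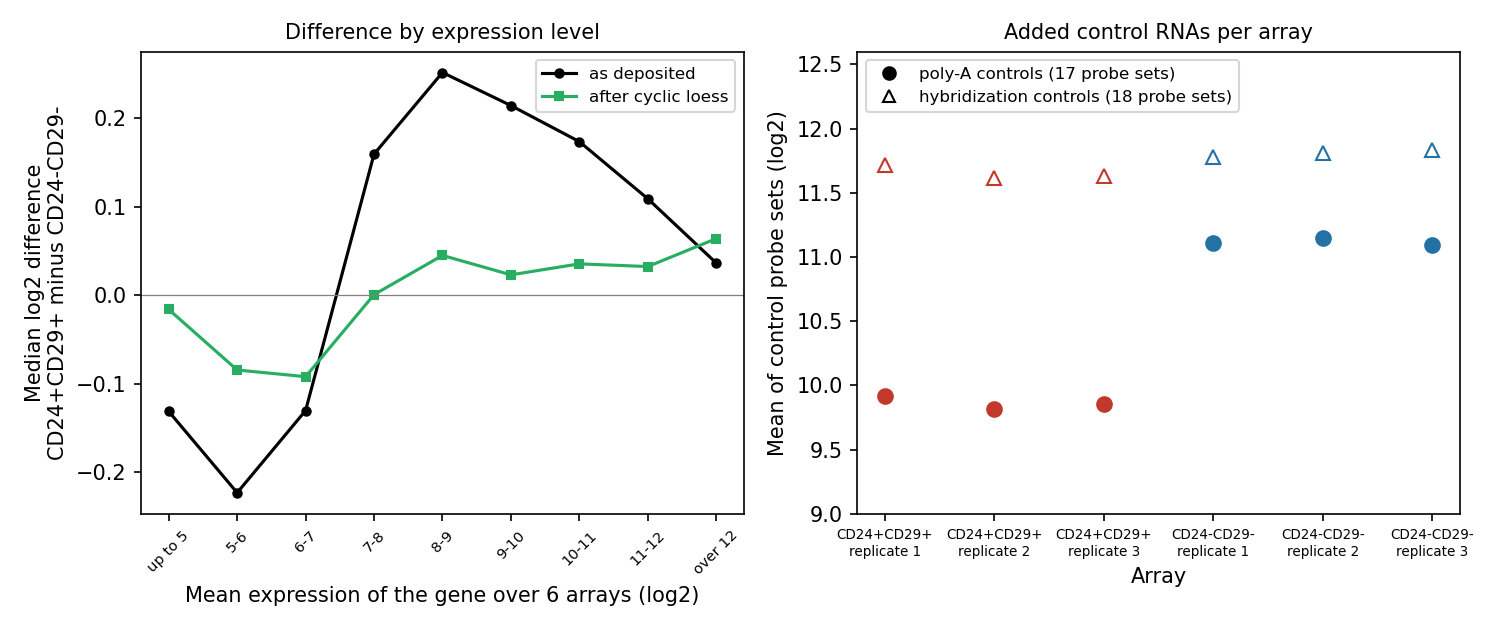
Left, the median log2 difference (CD24+CD29+ minus CD24-CD29-) of genes grouped by their mean log2 expression, as deposited (black) and after cyclic loess (green); the deposited values run from -0.22 at 5 to 6 to 0.25 at 8 to 9. Right, the mean log2 value per array of 17 poly-A control probe sets (filled circles) and 18 hybridization control probe sets (open triangles), red for CD24+CD29+ and blue for CD24-CD29-; the poly-A controls averaged 9.86 and 11.1.

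The next comparison asked whether genes of the mammary lineages, of the epithelial and mesenchymal states and of stem cells differed. Genes of basal and myoepithelial cells, the contractile outer layer of the mammary duct, were higher in CD24+CD29+ cells. Of 26 measured, 22 rose, 2 fell and 2 did not pass, with a median of 0.54. The caveola gene Cav1 was higher by 4.26-fold (log2 2.09, SE 0.05), the R-spondin receptor gene Lgr5 by 3.27-fold, Egfr by 2.45-fold and the hemidesmosomal collagen gene Col17a1 by 2.11-fold. Genes of luminal cells, the milk-producing and hormone-sensing inner layer, were lower relative to the other genes. Of 27, 7 rose, 19 fell and 1 did not pass, with a median of -0.27, which turned to 0.99 under scaling to the poly-A controls. The casein gene Csn1s1 was lower by 5.23-fold (log2 -2.39, SE 0.04), Csn3 by 2.17-fold and Elf5, a regulator of the alveolar lineage, by 1.96-fold, or higher by 0.29 under that scaling. Csn3 stood at 12.95 against 14.07, near the highest value on the arrays, where differences can be understated, so its size, and its direction under that scaling, are uncertain. The estrogen receptor gene Esr1 went against the list, 2.15-fold higher, although 1 of its 3 probe sets was lower. The adjusted p of camera was 1.3e-05 for the basal and 0.018 for the luminal list, and with an estimated correlation the adjusted p was 0.29 and 0.37.

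Genes of the mesenchymal state and of its induction (25) had 16 rises and 5 falls, with 4 not past the threshold and a median of 0.55. Besides Lox, the matrix genes Tgfbi and Tnc were higher by 3.41-fold and 3.28-fold and Mmp2 by 2.75-fold. Fibroblast markers were higher on the same arrays, by a median of 0.55. Of transcription factors that induce this state, chosen after their values were seen, Snai2 was higher by 0.67 and Snai1, Twist1 and Zeb2 were lower, at -0.54, -0.22 and -0.28, differences that turn positive under scaling to the poly-A controls; Zeb1, at -0.19, did not pass. By camera the adjusted p was 0.0045, and the adjusted p was 0.37 with an estimated correlation. Over 17 other settings camera's adjusted p ran from 0.00057 to 0.088, and scaling to the poly-A controls ended the call. Because that scaling adds the same amount to every gene, the list's median relative to all genes, 0.59, could not change. It therefore does not bear on the lost call. Genes of epithelial adhesion and junctions split into 15 rises and 16 falls of 35 (median -0.01, or 1.25 under scaling to the poly-A controls, but mean 0.02, and the test's direction was up; camera adjusted p = 0.85). Stem cell and pluripotency genes split into 15 rises and 13 falls of 33, or 15 and 14 when adjusted over the list alone (median 0.06, or -0.07 with the mean of a gene's probe sets; camera adjusted p = 0.85). Hmga2, which encodes a chromatin protein, was higher by 2.13-fold and Cd44, a hyaluronan receptor gene, by 1.59-fold, while the dehydrogenase gene Aldh2 was lower by 1.59-fold, or higher by 0.59 under scaling to the poly-A controls.

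The title's subjects, PI3K and mTOR signalling and the cytoskeleton, gave a mixed picture. Of 60 PI3K, AKT and mTOR genes, 29 rose, 19 fell and 12 did not pass (30 and 20 when adjusted over the list alone), with a median of 0.15, at percentile 58.4 among random lists matched on level. Akt1, the kinase downstream of PI3K, was 2.82-fold higher (10.57 ± 0.03 against 9.08 ± 0.05, SD, n = 3) on its brightest probe set, with a dim probe set of the opposite sign. The insulin receptor substrate gene Irs1 was 2.14-fold higher and the growth factor gene Igf2 2.06-fold, whereas Rragd had the largest fall of the list's members. The list did not pass camera (adjusted p = 0.10, and 0.63 with an estimated correlation), and of 17 other settings, which gave an adjusted p of 0.038 to 0.98, it passed with the mean of a gene's probe sets.

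Of 77 genes of actin remodelling, 46 rose, 16 fell and 15 did not pass (46 and 17 when adjusted over the list alone), and the median was 0.23. Differences were small: 1 gene rose and 1 fell by at least 2-fold. The list's median level was 10.46, and of all 1567 genes with a mean of 10 to 11, 867 rose and 373 fell. The counts alone therefore do not set the list apart, while its median difference lay at percentile 99.5 among random lists matched on level. Gsn, which encodes the actin-severing protein gelsolin, was 2.42-fold higher on its main probe set, but 3 brighter probe sets ending in _x_at were at -0.26, -0.20 and -0.10, the last not past the threshold, and its other probe sets did not pass. The kinase gene Limk2 and the phosphatase gene Ssh2, which act on cofilin in opposite directions, were higher by 1.78-fold and 1.63-fold, Limk2 with 1 dim probe set of the opposite sign, and the haematopoietic GTPase gene Rac2 was lower by 3.68-fold. By camera the adjusted p was 0.014, and the adjusted p was 0.51 with an estimated correlation. The call was also lost under either filter on dim genes, cyclic loess, the mean of probe sets and scaling to the poly-A controls, in a range of 0.010 to 0.26. Of 40 genes of integrins and focal adhesion, 24 rose, 9 fell and 7 did not pass (median 0.27, percentile 99.1 among matched lists). Their median level was 9.86, and of all 2239 genes with a mean of 9 to 10, 1292 rose and 498 fell. Itga7 and Itgb4, laminin receptor chains, were higher by 3.36-fold and 2.27-fold, and the focal adhesion kinase relative Ptk2b by 2.15-fold on the brighter of 2 probe sets that differed in sign. The adjusted p of camera was 0.014, and the adjusted p was 0.37 with an estimated correlation; it ran from 0.012 to 0.11 over 17 other settings, and either filter on dim genes or scaling to the poly-A controls ended the call. Genes of tubulins and microtubule regulators, 14 higher and 7 lower of 26, did not pass (median 0.16, or -0.02 without the dimmest 40% of genes; camera adjusted p = 0.16).

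Genes of the extracellular matrix were mostly higher in CD24+CD29+ cells. Of 43 collagens, laminins and other matrix genes, 37 rose, 3 fell and 3 did not pass, with a median of 0.92, and 18 rose by at least 2-fold. Fibroblast markers, 6 of which this list also holds, were higher on the same arrays (12 of 19, median 0.55, camera adjusted p = 0.0042, and the adjusted p was 0.32 with an estimated correlation), while the 13 markers outside the list had a median of 0.07. Besides Col6a1, the laminin chain gene Lama3 was higher by 4.62-fold (log2 2.21, SE 0.05; 1 dim probe set differed in sign), Fbln5, which organises elastic fibres, by 3.72-fold and Col6a2 by 3.29-fold. For this list camera's adjusted p was 1.3e-10, and the adjusted p was 0.29 with an estimated correlation. Of 40 genes in the list of matrix proteases and their inhibitors, 31 rose, 6 fell and 3 did not pass (median 0.57). Mmp10, Mmp3 (3.88-fold) and Adam8 rose, as did Lox, a crosslinking enzyme and not a protease that the list also holds, and Mmp16 and Ctss fell. Here camera's adjusted p was 2.5e-06, and the adjusted p was 0.29 with an estimated correlation. Scaling to the poly-A controls ended the call, in a range of 2.7e-07 to 0.37 over 17 other settings. The median relative to all genes, 0.61, could not change under that scaling, so it does not bear on the lost call.

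Proliferation genes were also higher. Of 40 genes of the G1 and S phases, 37 rose, 2 fell and 1 did not pass, with a median of 0.75, and of 39 genes of the G2 and M phases 37 rose and 2 fell, with a median of 0.99. Both medians lay above those of the matched random lists (percentile 100), and after cyclic loess they were 0.59 and 0.87. The cyclin gene Ccnd2 was higher by 2.55-fold, the replicative helicase gene Mcm4 by 2.31-fold, E2f8 by 2.28-fold and Cdc45 by 2.34-fold, with 1 dim Cdc45 probe set of the opposite sign. Prc1, which bundles spindle microtubules, was higher by 4.49-fold (log2 2.17, SE 0.04), Cdk1 by 3.66-fold, Top2a by 3.50-fold and the cytokinesis gene Anln by 3.01-fold. Of 40 genes of DNA damage response and repair, 30 rose, 2 fell and 8 did not pass (median 0.38). Rad54l was higher by 2.71-fold and the histone variant gene H2ax by 2.11-fold, as were the checkpoint kinase gene Chek1 (2.26-fold) and Fanca (2.09-fold), each with 1 dim probe set of the opposite sign. Camera's adjusted p was 9.1e-11 for G1 and S, 4.5e-12 for G2 and M and 3.9e-05 for repair, and the adjusted p was 0.32, 0.29 and 0.37 with an estimated correlation.

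Several signalling lists also passed camera as higher, but the medians of the Hedgehog and hypoxia lists lay inside the central 95% of random lists matched on level (percentiles 93.6 and 76.9). Of 27 Hippo pathway genes and YAP targets, 19 rose, 5 fell and 3 did not pass (median 0.48). Nt5e and the membrane repair gene Myof were higher by 2.53-fold and 2.35-fold, with 1 dim Nt5e probe set of the opposite sign, and the transcription factor gene Tead1 by 1.89-fold, while the coagulation factor gene F3 was lower by 3.34-fold. Of 44 TGF-beta and BMP genes, 27 rose, 12 fell and 5 did not pass (28 and 12 when adjusted over the list alone), with a median of 0.30, at percentile 99.2 among matched lists. Their median level was 9.93, and of all 2239 genes with a mean of 9 to 10, 1292 rose and 498 fell. The ligand genes Bmp6 and Bmp7 were higher by 2.95-fold and 2.27-fold and Inhbb by 1.81-fold, and Bmp1, which encodes a protease that processes collagen, by 2.86-fold with a dim probe set of the opposite sign. Of 15 Hedgehog genes, 10 rose, 2 fell and 3 did not pass (median 0.33), led by Gli3 (1.92-fold), Smo (1.35-fold) and Kif7 (1.32-fold). Sufu was 1.29-fold higher on its main probe set, but 2 of its 3 probe sets passed in the opposite direction. The mean of its probe sets gave -0.08, which did not pass. Of 33 genes of hypoxia and glycolysis, 19 rose, 6 fell and 8 did not pass (median 0.13). P4ha1 and P4ha2, collagen prolyl hydroxylases, were higher by 1.87-fold and 1.96-fold and the carbonic anhydrase gene Car9 by 1.86-fold, whereas Adm was 2.22-fold higher on its main probe set and lower, at -0.16 on a brighter one ending in _x_at. Camera's adjusted p was 0.0045 for Hippo, 0.015 for TGF-beta, 0.026 for Hedgehog and 0.020 for hypoxia, and the adjusted p was 0.46, 0.37, 0.37 and 0.46 with an estimated correlation. None of these lists passed under either filter on dim genes. Scaling to the poly-A controls ended the call of Hippo, TGF-beta and Hedgehog, keeping probe sets ending in _x_at that of hypoxia, and quantile normalization, cyclic loess or the mean of probe sets that of Hedgehog; over 17 other settings the adjusted p ran up to 0.24 for Hippo, 0.34 for TGF-beta, 0.24 for Hedgehog and 0.29 for hypoxia.

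Markers of other cell types were also compared. Of 19 fibroblast markers, 12 were higher in CD24+CD29+ cells, 1 was lower and 6 did not pass (median 0.55), led by Col1a2 (4.07-fold), Col3a1 (3.31-fold), Lum (2.78-fold) and Dcn (2.22-fold), which the matrix list also holds. Of the 13 markers outside the matrix list, 6 were higher and 1 lower, with a median of 0.07. Of 28 leukocyte markers, 19 were lower, 1 was higher and 8 did not pass (1 higher and 20 lower when adjusted over the list alone), with a median of -0.32, or 0.94 under scaling to the poly-A controls. The antigen presentation genes H2-Aa, H2-Ab1 and Cd74 were lower by 3.68-fold, 3.01-fold and 2.99-fold, and Csf1r by 1.84-fold, or higher by 0.38 under that scaling. All 6 erythroid markers were lower, with a median of -0.38, or 0.88 under that scaling. The median lay inside the central 95% of matched random lists (percentile 3.81), and genes with a mean of 5 to 6 had a median of -0.22. Among the markers were Gata1 (1.49-fold), Hba-a1 (1.33-fold), Alas2 (1.32-fold) and Epb42 (1.28-fold lower), and all 4 named had means under 6. Camera's adjusted p was 0.0042 for fibroblast, 0.00057 for leukocyte and 0.027 for erythroid markers, and the adjusted p was 0.32, 0.29 and 0.37 with an estimated correlation; scaling to the poly-A controls ended the fibroblast call (0.00043 to 0.14 over 17 other settings), and quantile normalization, cyclic loess or that scaling ended the erythroid call (0.019 to 0.67 over 15). Endothelial markers (6 higher and 4 lower of 22, median 0.01) and adipocyte markers (1 higher and 7 lower of 11, median -0.23, or 1.03 under scaling to the poly-A controls) did not pass, with camera adjusted p of 0.76 and 0.16.

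**Figure D3:**
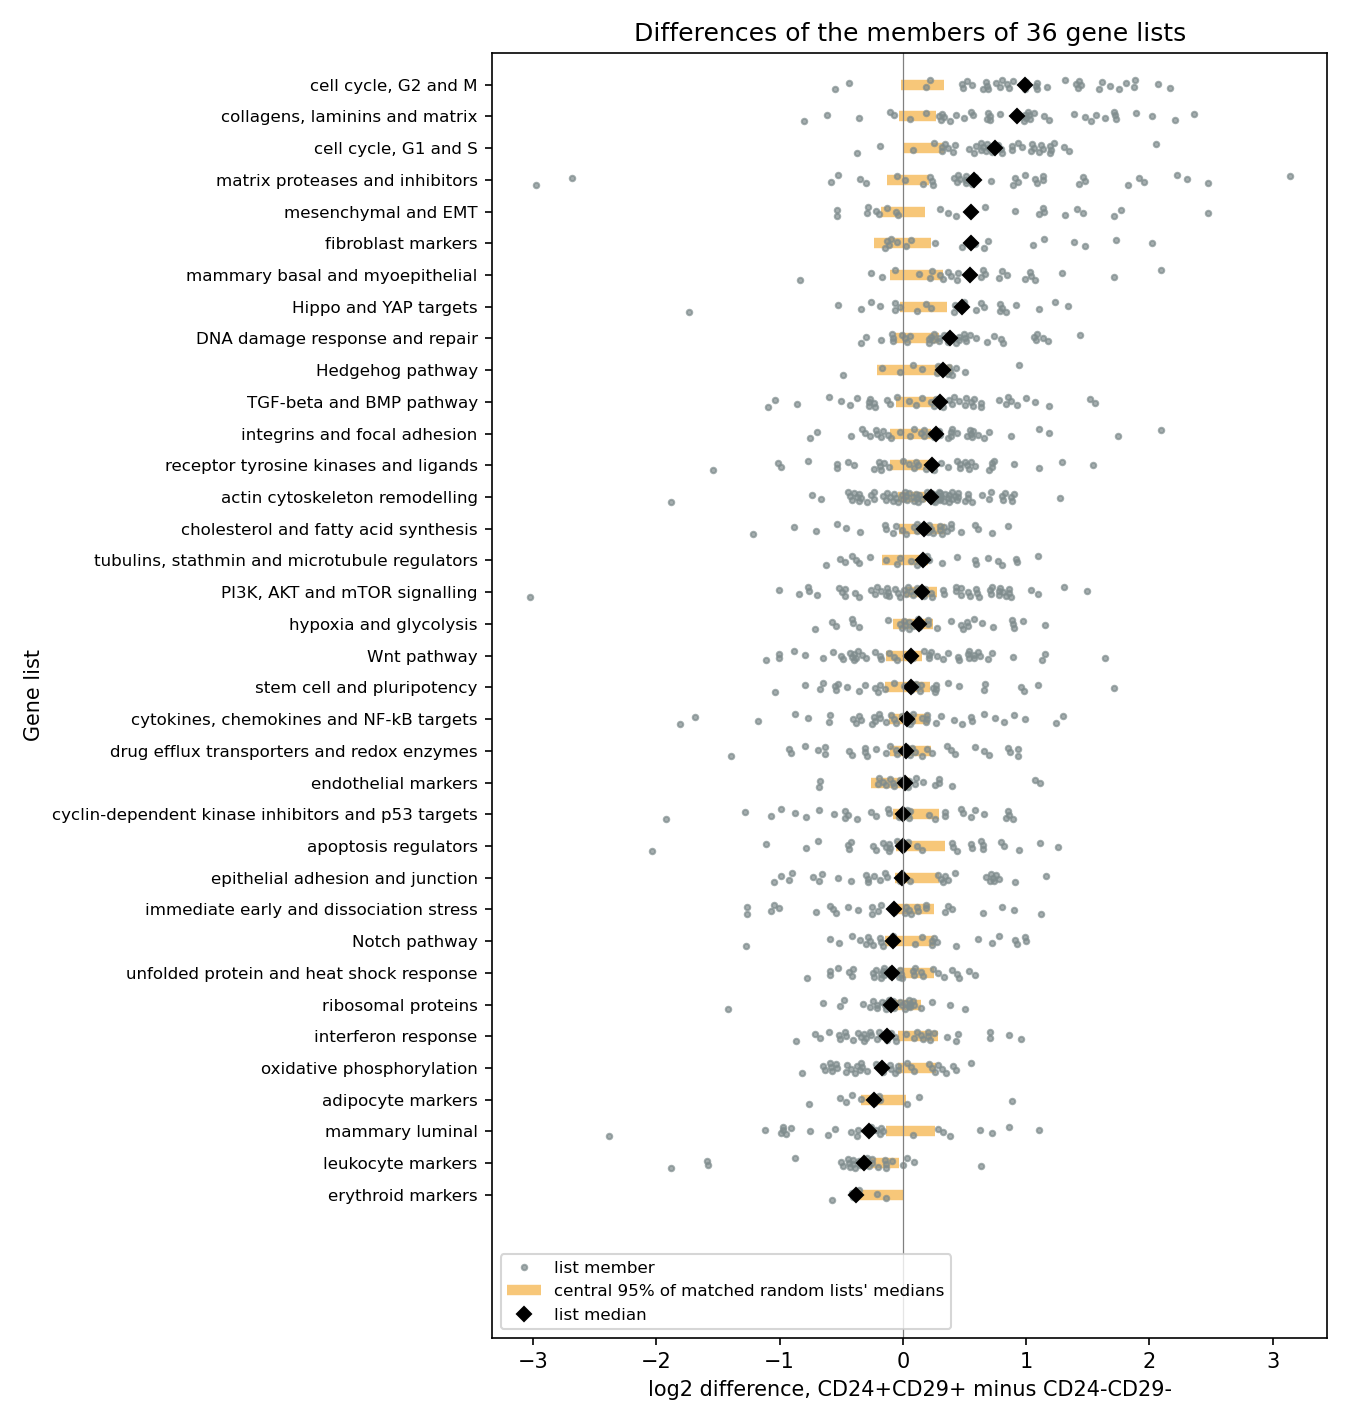
Log2 difference (x axis, CD24+CD29+ minus CD24-CD29-, as deposited) of each measured member (grey points) of 36 gene lists; black diamonds are list medians and amber bars the central 95% of the medians of 10000 random lists matched on level. The medians run from 0.99 for G2 and M genes to -0.38 for erythroid markers; scaling to the poly-A controls makes the medians of all 36 lists positive.

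With the preset correlation, 17 of the 36 lists passed camera, 14 higher and 3 lower. Their medians lay outside the central 95% of matched random lists, except those of the Hedgehog, hypoxia and erythroid lists. With an estimated correlation 0 passed camera after adjustment (adjusted p = 0.29 or more for each) and 5 had an unadjusted p under 0.05. By comparison, 33 passed fry, which asks whether the genes of a list move one way, on balance, and not whether they move more than other genes. Where counts adjusted over a list alone are not given for a list above, they equalled those over all genes, except for repair, integrins and endothelial markers, which had 30 and 3, 24 and 10, and 6 and 3 higher and lower.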

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

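The limit on the brightness of 3' probe sets and the tests of labelling, hybridization brightness, pipetting and the amount of cell mRNA were chosen after the results were seen, and the leukocyte tests were chosen when the list's median was known.

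Control probe sets, and probe sets with no gene symbol, also differed between the groups. The 17 poly-A control probe sets with a mean of 13 or less, which read bacterial RNAs added before labelling, were higher on CD24-CD29- arrays by a median of 1.24 on the log2 scale, a 2.36-fold difference with a range of 0.90 to 1.55. The 3' to 5' ratio of beta-actin was higher on those arrays by 1.03, but its 3' probe set stood at 14.2 against 14.5 on CD24+CD29+ arrays, near the highest value on any array, where differences can be compressed, so the ratio was not used as a measure of RNA quality. The 3 control probe sets for 18S rRNA were higher on CD24-CD29- arrays by a median of 0.48. Of 9160 probe sets with no gene symbol here, 148 differed by at least 2-fold, 100 higher and 48 lower in CD24+CD29+ cells.

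The first pattern weighed was that dim genes were lower and bright genes higher on CD24+CD29+ arrays. A difference in scale left by the normalization would raise controls of the same brightness too, but hybridization controls of level 8 to 11 moved by -0.20, the other way. All 18 hybridization controls, at every level, were higher on CD24-CD29- arrays, so an offset of their own could hide such a rise. The controls cannot decide, and a difference in scale stays open. A less complete labelling reaction in CD24-CD29- stays open. The 8 ratios of 3' to 5' probe sets read the added dap, lys, phe and thr RNAs more than once each. They were higher in CD24+CD29+, the other way, by 0.0091 to 0.99 (median 0.28). Those of 0.0091 and 0.078 were not beyond the spread (exact permutation test, 2-sided, p = 0.8 and 0.2). Compression near the highest value can set that direction, and 1 ratio, at 0.0091, had a 3' mean of 13 or less in both groups. Middle probe sets of 13 or less gave no single direction against the 5' ones. The differences were -1.26 against -1.52 for LysX, but -1.18 against -0.95 for ThrX. More degraded RNA in one group stays open too, because the 3' probe sets of beta-actin (ratio difference 1.03) and Gapdh (0.068, where at least 0.5 was predicted for both) stood above 13. Control probe sets of cell RNAs at 13 or less, compared after their values were seen, gave no single direction. The differences, CD24+CD29+ minus CD24-CD29-, were 0.36 for the middle and 0.24 for the 5' Gapdh probe set. At the 3' and 5' ends they were -0.25 and -0.08 for pyruvate carboxylase, and 0.30 and -0.09 for the transferrin receptor. The 5' probe sets of these last controls were dim, with means of 5.69 and 4.52. A difference in transcription between the sorted cells also stays open and was not tested apart from these explanations.

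The next pattern was the higher poly-A controls on CD24-CD29- arrays, at a mean per array of 11.1 ± 0.03 against 9.86 ± 0.05 (SD, n = 3; exact permutation test, 2-sided, p = 0.1, the smallest possible). Brighter hybridization is argued against by the hybridization controls, which differed by a median of 0.14. Separate pipetting errors on each array are argued against by the spread, since the larger SD within a group was 0.040 of the difference between groups. Less cell mRNA per amount of RNA labelled in CD24-CD29- would give the difference of 1.24, but so would another dilution of the controls for each group, and the pair cannot be told apart, because no measure of cell mRNA apart from the controls was used here. The 3 probe sets for 18S rRNA were also higher on those arrays, by a median of 0.48 (0.15 to 0.55). They read rRNA and not cell mRNA, so they cannot decide between the pair.

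The last pattern was that leukocyte markers were lower in CD24+CD29+ cells. The level-dependent shift is argued against as the whole cause, since the list's median of -0.32 lay at percentile 0.44 among random lists matched on level, and after cyclic loess it was -0.23 with a camera adjusted p of 0.0098, the highest of 17 other settings with the preset correlation, which went down to 1.4e-06; the call was lost with an estimated correlation (adjusted p = 0.29). Leukocytes among the CD24-CD29- cells may account for it, and 7 genes abundant in leukocytes had a median difference of -0.39, between the bounds of -0.5 and -0.3 set beforehand. By the other bound, on level, 1 of the 7 lay above 7 in CD24-CD29- cells (Cd74, 8.47), which counted against leukocytes, but Laptm5, at 6.89 ± 0.09, lay within 2 SD of it, a margin added after the values were seen, and 5 of the 7 fell, so this stays open. Outside these 7, the list members H2-Aa, H2-Ab1 and Csf1r, named for their small p, stood at 7.04, 7.59 and 7.63 in CD24-CD29- cells. Of all 28 members, 1 was higher in CD24+CD29+ cells and 8 did not pass. Ptprc, on nearly all leukocytes, was at 4.85 against 4.94 and did not pass, Coro1a was higher by 0.63, and no sort step against leukocytes is named in the labels.

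For the splits of the 6 arrays into 3 and 3, of which there are 10, a share under 0.1 is impossible, so they are too few for a test. The groups gave 12889 genes past the threshold, 849 of at least 2-fold, and 17 lists. For each count 1 of the 10 splits, the real one, gave a value as large, and the highest of the other splits gave 0, 0 and 14. The other splits called 6 to 14 lists with camera's preset correlation. Each of them mixes the groups on both sides, so it keeps part of the group difference and adds the rest to the spread. The matrix list's median, for example, still reached 0.32 in size, against 0.92 in the real split. The 0 genes therefore follow from the mixing, and the 6 to 14 lists are not a rate of false calls.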

How the results depend on the processing

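Cyclic loess and scaling to the poly-A controls were chosen after the results were seen.

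Of the 94 named genes, 89 kept their direction and call in each setting that gave them a value, scaling to the poly-A controls aside, and 81 with that scaling included. The equal-variance test was read for its counts and not for the named genes. Genes left out by a filter on dim genes, among them Gata1, Hba-a1, Alas2 and Epb42, had no value there. With one array left out in turn, 11758 to 12407 genes passed, and 826 to 889 by at least 2-fold. The lists for basal, luminal, matrix, G1 and S, G2 and M, repair and leukocyte genes passed camera in all 17 other settings with the preset correlation, and each was lost with an estimated one (adjusted p = 0.29 to 0.37). Lists that passed in other settings alone were PI3K in 1, oxidative phosphorylation in 5, interferon in 4, and the unfolded protein, immediate early and ribosomal lists in 2 each, the filters on dim genes. An equal-variance test per gene called 11275 genes. The replicate number as a block gave 12867 genes, 12471 of them shared with the fit without it, and 849 by at least 2-fold; deviations of same-numbered arrays correlated at 0.22, -0.05 and 0.04, so the numbers were not taken to pair the samples. Dim genes are limited by background. The adipocyte and erythroid lists had under 5 genes left under either filter on dim genes and gave no value there.

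Fewer dim genes tested gave fewer lower genes, 2966 without the dimmest 40% and 3485 without means under 6. Every probe set tested, which adds features, gave 28786 past the threshold, 13135 higher and 15651 lower, and 1547 by at least 2-fold, 1030 and 517. The mean of a gene's probe sets gave 539 genes of at least 2-fold, 332 higher, and turned Cd24a to -0.015 (adjusted p = 0.75) and Sufu to -0.084. Keeping probe sets ending in _x_at turned Adi1 to 0.40, Gsn to -0.26 and Adm to -0.16, since a brighter probe set then stood for the gene. In place of the preset correlation, an estimated one left 0 lists, 5 at an unadjusted p under 0.05, and fry gave 33.

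Scaling to the poly-A controls adds the same amount to each difference, so no list's median relative to all genes moved, also where a call was lost. It gave 17948 higher and 122 lower genes, 13319 by at least 2-fold, 13293 higher and 26 lower, and 8 lists. It turned Csn3, near the highest value on the arrays, to 0.14, Elf5 to 0.29, Csf1r to 0.38, Gata1 to 0.69, Hba-a1 to 0.84, Alas2 to 0.86, Epb42 to 0.90 and Aldh2 to 0.59.

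Lists that did not pass changed the direction of camera's test in some settings, with none past the threshold in either, and the cause was not tested. Without the dimmest 40% the adjusted p was 0.355 for epithelial adhesion, 0.958 for PI3K, 0.649 for tubulins and for apoptosis, 0.771 for stem cell genes, 0.963 for Wnt, 0.664 for cytokines and 0.793 for cholesterol. Without means under 6 it was 0.552 for epithelial adhesion, 0.995 for tubulins and for cholesterol, 0.679 for stem cell genes, 0.968 for Notch, 0.748 for apoptosis and 0.632 for cytokines. After quantile normalization it was 0.883 for epithelial adhesion and 0.950 for Notch, cytokines and cholesterol. With the mean of probe sets it was 0.968 for epithelial adhesion and for kinase inhibitors with p53 targets, and 0.871 for cytokines, and with _x_at kept 0.948 for cytokines. After cyclic loess it was 0.862 for epithelial adhesion, 0.958 for Notch and for cytokines, and 0.864 for cholesterol. Under scaling to the poly-A controls it was 0.768 for apoptosis, 0.705 for interferon, 0.370 for cytokines, 0.375 for oxidative phosphorylation, 0.367 for unfolded protein, 0.761 for ribosomal and 0.712 for endothelial genes.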

Other observations

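No further explanations were tested here; the genes named in this part were chosen after their values were seen.

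Each list of stress and growth arrest genes held rises and falls and did not pass camera, but the medians of 3 of them, immediate early, unfolded protein and interferon genes, lay below the central 95% of random lists matched on level. That range leaves out correlation between a list's genes, estimated at 0.15, 0.075 and 0.072 for these lists, and can be too narrow. Of 34 genes of cyclin-dependent kinase inhibitors and p53 targets, 13 rose and 15 fell in CD24+CD29+ cells (median 0.00, or -0.16 after cyclic loess, but mean -0.09, and the test's direction was down; camera adjusted p = 0.76). Gadd45a and Trp53inp1, induced by p53, were lower, at -1.92 and -1.28 and the kinase inhibitor gene Cdkn1a by -0.68, whereas Cdkn2a and Cdkn2c were higher by 0.84 and 0.85. Apoptosis genes had 13 rises and 11 falls of 33 (median 0.00, or -0.02 after cyclic loess, mean 0.07; camera adjusted p = 0.67). The killer gene Bik fell by 2.03 and the survival gene Bcl2l1 by 1.11 on the log2 scale, and the inhibitor of apoptosis gene Birc3 was higher by 1.26. Immediate early and dissociation genes had 11 rises and 15 falls of 34 (median -0.07, percentile 1.19 among matched lists, camera adjusted p = 0.31), with Nr4a2 and Maff lower, at -1.27 and -1.26 and Junb higher by 1.12. Genes of the unfolded protein and heat shock response had 8 rises and 16 falls of 36 (median -0.09, percentile 0.63, camera adjusted p = 0.42), led by the chaperone gene Dnaja1 at -0.78. Of 39 interferon genes, 12 rose and 18 fell (13 and 19 when adjusted over the list alone; median -0.12, percentile 0.37, camera adjusted p = 0.31), with Irf1 at -0.86 and Cxcl10 at 0.96. Cytokine, chemokine and NF-kB genes had 17 rises and 16 falls of 43 (median 0.03, or -0.03 after cyclic loess, mean -0.00; the test's direction was up, camera adjusted p = 0.85). The adhesion gene Vcam1 and the chemokine receptor gene Cxcr4 were lower, at -1.81 and -1.69, and Ptgs2 was higher by 1.30.

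Signalling and metabolic genes were mixed as well. Wnt genes had 21 rises and 20 falls of 47 (median 0.07, camera adjusted p = 0.76), with the secreted modulators Dkk3 and Sfrp2 higher by 1.64 and 1.16 and the receptor gene Fzd5 lower, at -1.11. Notch genes had 13 rises and 10 falls of 30 (13 and 11 when adjusted over the list alone; median -0.08 but mean 0.08, and the test's direction was up, camera adjusted p = 0.76). The Notch targets Hey1 and Hes1 moved apart, at -1.28 and 0.93. Receptor tyrosine kinase and ligand genes had 23 rises and 12 falls of 41 (median 0.23, percentile 97.6 among matched lists, camera adjusted p = 0.16), with Axl higher by 1.10 and Efnb2 lower, at -1.54. Of 37 genes of oxidative phosphorylation, 9 rose and 20 fell (median -0.17, percentile 0.01 among matched lists). The list did not pass camera (adjusted p = 0.056), but it passed in 5 of 17 other settings, which ranged from 0.0010 to 0.37, 1 of them without CD24+CD29+ replicate 1 (0.038). Genes of cholesterol and fatty acid synthesis had 15 rises and 8 falls of 32 (16 and 8 when adjusted over the list alone; median 0.17, or -0.01 after cyclic loess, camera adjusted p = 0.30), with Insig1 at -1.21. Genes of drug efflux and redox enzymes had 13 rises and 14 falls of 35 (median 0.02, or -0.00 after cyclic loess, but mean -0.02, and the test's direction was down, camera adjusted p = 0.85), with Gpx2 at -1.39 and the efflux pump gene Abcg2 at -0.80. Ribosomal protein genes had 4 rises and 16 falls of 34 (4 and 15 when adjusted over the list alone; median -0.09, percentile 0.99 among matched lists, camera adjusted p = 0.16). Under scaling to the poly-A controls the medians of all 13 lists named in this part were above 1, and falls smaller than 1.26, the controls' mean difference, became rises.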
